A study of Mus musculus with 8 samples.

How the data were processed

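RNA was measured in 8 libraries of stromal cells from mouse small intestine. The cells lacked CD45, a marker of haematopoietic cells, and CD31, a marker of endothelium, and were sorted by flow cytometry on the YFP signal of LTβR-YFP mice, whose marker is named after the lymphotoxin beta receptor. There were 4 libraries per gate. Per the labels' protocols, libraries were made with a stranded total RNA kit for very small inputs and sequenced on an Illumina NextSeq.

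Per the submitters' processing notes, cutadapt 3.4, STAR 2.7.3a, featureCounts 2.0.1 and DESeq2 were used, and the notes name the GRCm38 (mm10) build. The DESeq2 version and the strand setting of the counting are not given in the sources used here. The authors' deposited table holds raw counts per gene and library, which were whole numbers and were not normalised. The same deposited table gives log2 fold changes of YFP+ over YFP- and adjusted p-values for that comparison. Its normalised columns were not used here.

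The labels conflict. In all 8 samples the title gives the opposite YFP sign to the description and the genotype. Groups were taken from the description, which agrees within each sample with the genotype and with the names of the count columns. Every direction below therefore rests on the description and genotype, and would turn over if the titles were right. Ltbr RNA did not differ between the groups and so could not decide between the labels.

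Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 53801 genes, 23010 had no count in any library and 16354 passed edgeR's expression filter. Libraries were scaled by TMM and compared by the quasi-likelihood F test without a block, with robust estimation and Benjamini-Hochberg adjustment at a threshold of 0.05. CPM were computed from the deposited counts with the TMM-scaled totals. The SE of a log2 fold change was back-computed as its absolute value divided by the square root of the F statistic. Library totals ran from 23272858 to 29829232 counts. The pairs of libraries all differed by more than sampling noise, so each was counted as 1 replicate. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

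Gene lists (28) were fixed before the data were examined. The 27 lists with at least 5 tested members were compared with the other genes by camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. Named genes followed a rule fixed at the same time. It took Ltbr, then the 6 largest changes in each direction among called genes with a mean of at least 10 CPM and no overlap between the groups, leaving out genes without a symbol, predicted genes, pseudogenes and antisense genes. From each list of stromal biology it took up to 2 called genes per direction by smallest p, or the most abundant member where none was called. From each list of other cells or RNA quality it took the 2 most abundant members. Genes named outside this rule are said to be so, and some genes that the rule took are not reported here.

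Equal replicate numbers were checked for pairing. Over 5200 genes with a mean log2 CPM above 5, deviations from the group means correlated across genes at 0.60, 0.64, 0.38 and 0.57 for libraries with the same number. Pairs with different numbers ran from -0.42 to 0.05. The numbers were therefore taken to pair the samples, although no label states what they share. Values with the replicate number as a block are given where they change a call or move a count by more than 1.5 times. The main test left this pairing out, and 697 genes passed in it against 1880 with the block. A gene that did not pass in the main test may therefore pass with the block. DESeq2 1.42.0 fitted with the replicate number and the group gave the deposited log2 fold changes to within 0.0005, while the fit without the number differed by a median of 0.0499.

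Alternatives were relative log expression and upper-quartile scaling, no filter, a filter of 1 CPM in 4 libraries, DESeq2, limma-voom, the replicate block, removal of mitochondrial and ribosomal RNA genes, and removal of each library in turn. DESeq2 with the block and removal of both libraries numbered 2, with and without the block, were added after seeing the data. The test was tried on simulated data drawn from these libraries' means and totals (YFP+ against YFP-, 16036 genes tested). It recovered 91.1% and 92.0% of genes planted at log2 fold changes of -2 and 2, and 59.2% and 61.2% of those at -1 and 1. Of its calls, 6.41% were false. The simulated libraries were not paired and their planted changes were balanced in direction, unlike these data, so the shares may differ here.

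Coordinates are 1-based on GRCm38 from GENCODE mouse release 21, which held 53706 of the 53801 gene identifiers. Of the named genes, 16 share exonic sequence with another annotated gene, 15 of them on the opposite strand, and their counts are uncertain to that extent.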

Results

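Stromal cells of the mouse small intestine that lacked CD45 and CD31 were sorted into YFP+ and YFP- fractions from LTβR-YFP mice, and RNA was sequenced from 4 libraries of each. Totals ran from 23272858 to 28688906 counts in YFP- and from 23404630 to 29829232 counts in YFP+. The question was how the stromal cells that carry the YFP marker differ in RNA from those that do not. Groups are those of the sample descriptions and genotypes, which the sample titles contradict in all 8 samples, so YFP+ and YFP- below mean the libraries labelled so by description and genotype.

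Ltbr, which encodes the lymphotoxin beta receptor, did not differ detectably between the fractions. Its level was 56.6 ± 1.27 CPM in YFP+ (SD, n = 4) and 52.4 ± 6.85 CPM in YFP- (SD, n = 4), a log2 fold change of 0.11 with an SE of 0.10 and an edgeR adjusted p of 0.654. Ltbr (ENSMUSG00000030339) lies on chromosome 6 from 125306571 to 125313885 on the minus strand. The gene therefore gave no check of which label was right.

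Genes of enteric glia, the support cells of the gut nervous system, were far lower in YFP+, and this was the largest difference among the gene lists. Of 11 tested glial genes, 10 fell, with the same count adjusted over the list alone, and the list median was -3.52 on the log2 scale. Kcna1, a voltage-gated potassium channel, stood at 0.622 ± 0.108 CPM in YFP+ and 27.2 ± 7.56 CPM in YFP- (SD, n = 4 each), and Cdh19, a cadherin of glia and Schwann cells, at 1.71 ± 0.457 and 46.8 ± 10.6 CPM. Their log2 fold changes were -5.45 (SE 0.23, edgeR adjusted p = 1.7e-09) and -4.77 (SE 0.21, edgeR adjusted p = 1.33e-08), and both were lower in YFP+ in 4 of 4 same-numbered pairs. The list passed camera with an adjusted p of 0.0016 with an estimated correlation, and 0.0298 with the replicate block and an estimated correlation.

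Genes of intestinal epithelium were also lower. Of 19 tested genes 5 fell, or 13 adjusted over the list alone, and the block gave 8. Pigr, the epithelial receptor that transports IgA, had 1.66 ± 0.859 CPM in YFP+ and 13.1 ± 5.91 CPM in YFP- (SD, n = 4 each), a log2 fold change of -2.97 (edgeR adjusted p = 0.0044). Lgals4, the most abundant member, did not pass, with a log2 fold change of -0.19 (edgeR adjusted p = 0.533). The list's camera adjusted p was 0.0451 with an estimated correlation, and 0.169 with both the block and an estimated correlation.

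Over all genes, 547 were lower and 150 higher in YFP+ of the 16354 tested by edgeR's quasi-likelihood test. With the replicate number as a block the counts were 1283 and 597, and without YFP+ replicate 3 they were 339 and 88. Without YFP- replicate 3, 96 genes were higher. At least 2-fold changes were found in 240 genes, of which 227 were lower and 13 higher. Among the named genes, which needed a mean of at least 10 CPM for this ranking, the other largest falls included Nkain2 (log2 fold change -5.06) and L1cam (-5.05). L1cam is a neural cell adhesion molecule whose exons overlap Arhgap4 on the same strand. Slc35f1 (-4.76) and Kcna2 (-4.66), another potassium channel, followed.

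**Figure D1:**
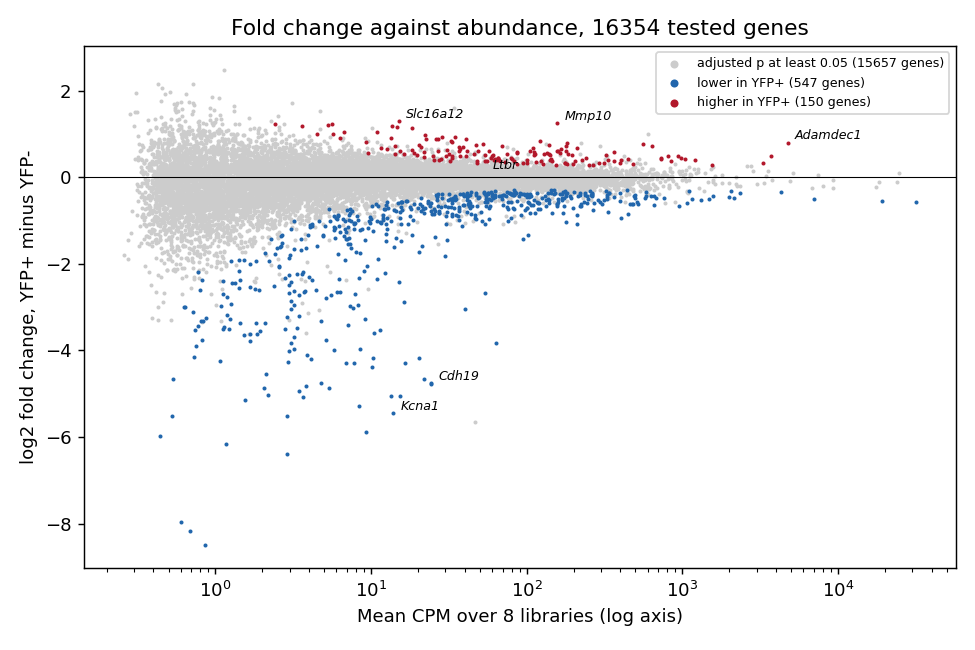
Log2 fold change (YFP+ minus YFP-) of each tested gene against its mean CPM over the 8 libraries, on a log axis; blue points are the 547 genes lower and red points the 150 genes higher in YFP+. Among the named genes the falls reach -5.45 for Kcna1 and the rises 1.30 for Slc16a12, and some genes of low CPM lie further out.

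The largest rises among the named genes were smaller than the largest falls. Slc16a12, a monocarboxylate transporter family member, was at 21.4 ± 2.49 CPM in YFP+ and 8.72 ± 0.930 CPM in YFP- (SD, n = 4 each), a log2 fold change of 1.30 (SE 0.14, edgeR adjusted p = 2.88e-05). Mmp10, a matrix metalloproteinase, had a log2 fold change of 1.25 (SE 0.19, edgeR adjusted p = 0.00468). Ogdhl followed at 1.19, Kcnk3, a potassium channel, at 1.16, and Sertm1 at 1.13. Adamdec1, a metalloproteinase gene of gut stroma named here after its values were seen, ranged from 5810 to 6562 CPM in YFP+ and from 3335 to 3677 CPM in YFP- (log2 fold change 0.80).

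**Figure D2:**
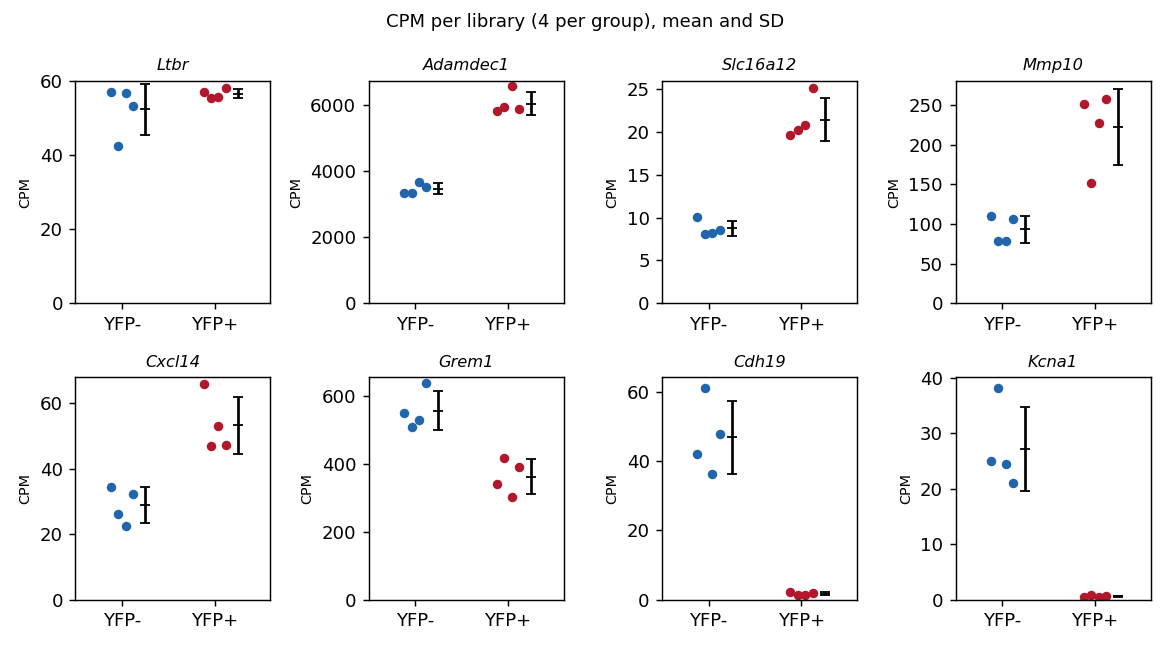
CPM per library of 8 genes, 4 libraries per group, with the mean and SD beside the points and each axis starting at 0. The groups overlap for Ltbr and are apart for the other genes shown, with Cdh19 at 46.8 CPM in YFP- and 1.71 CPM in YFP+ on average.

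Called fibroblast markers lay in different directions by list. Of 19 tested genes of the PDGFRa-high subepithelial fibroblasts, 6 rose and 1 fell, or 8 and 1 adjusted over the list alone and 9 and 2 with the block. Cxcl14, a chemokine, had a log2 fold change of 0.89, Nrg1, an epidermal growth factor family ligand, 0.84, and Wnt4 0.90, while Fbln1 fell by 0.47 on the log2 scale. The list's camera adjusted p was 1.2e-04 at the preset correlation and 0.0684 with an estimated correlation. Of 16 genes of the CD81+ crypt-base fibroblasts, 5 fell and 1 rose (9 and 3 adjusted over the list alone, 8 and 4 with the block). Cd81 had 38.7 ± 4.86 CPM in YFP+ and 75.3 ± 4.22 CPM in YFP- (SD, n = 4 each), a log2 fold change of -0.96. Grem1, a BMP antagonist, had a log2 fold change of -0.62, and Rspo3, a Wnt agonist, -0.65. Dkk3 was the member that rose (0.33). This list's camera adjusted p was 0.0451 with an estimated correlation and 0.336 with the block as well. Of 16 adventitial genes 5 fell and 1, Fn1, rose (6 and 1 adjusted over the list alone, 9 and 1 with the block). Pi16 had a log2 fold change of -1.47 and Ly6c1, uncertain because of its close copy Ly6c2, -0.90, and the list's camera adjusted p was 0.0503 with an estimated correlation. Pdgfra itself, named outside the rule, had a log2 fold change of -0.03 (edgeR adjusted p = 0.936).

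Smooth muscle and myofibroblast genes were higher in YFP+ by camera at the preset correlation but did not pass with an estimated correlation (camera adjusted p = 0.151, or 0.169 with the block as well). At the preset correlation 9 lists passed, a number that 6 of 35 splits of the libraries reached, the real one included. Of 17 tested, 5 rose and none fell, or 10 adjusted over the list alone and 15 with the block, and the estimate was positive for all 17. Myocd, a coactivator of smooth muscle genes, had a log2 fold change of 0.99 and Lmod1, a leiomodin, 1.04.

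**Figure D3:**
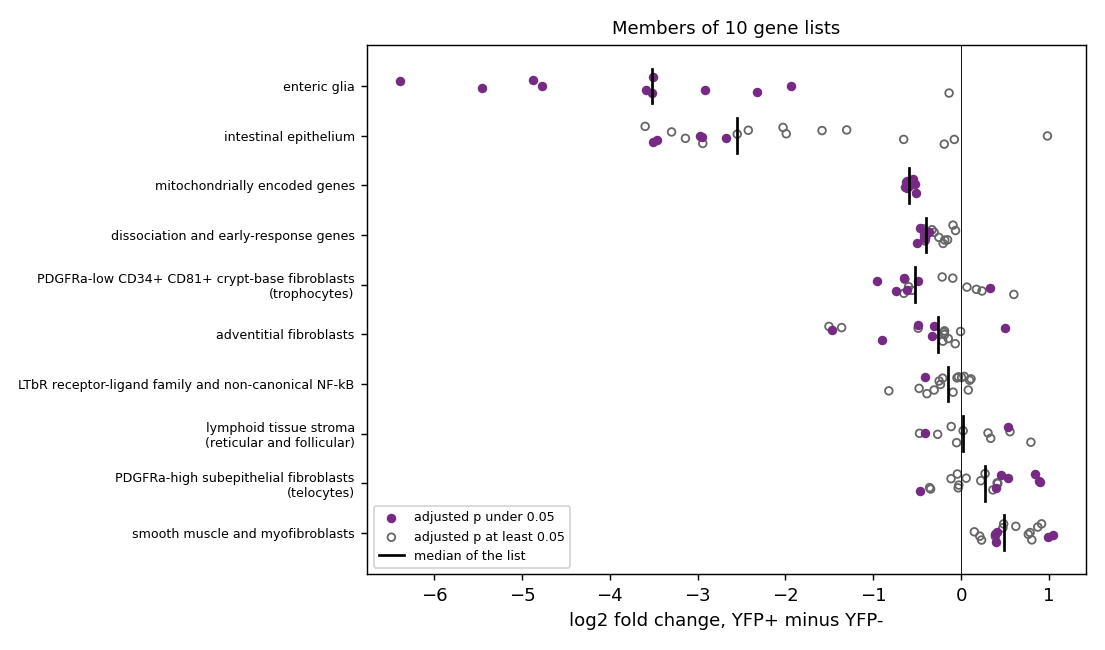
Log2 fold change (YFP+ minus YFP-) of each tested member of 10 gene lists, filled where the edgeR adjusted p was under 0.05, with a bar at the list median. The medians run from -3.52 for enteric glia to 0.48 for smooth muscle and myofibroblasts.

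Few genes of the list built around the receptor passed. Besides the LTβR ligand family and non-canonical NF-kB signalling, the list holds Tnfrsf1a, Tnfrsf1b, Nfkb1, Rela, Nfkbia and Tnfaip3, which are not specific to them. Of its 16 tested genes, Birc3, an inhibitor of apoptosis, was the 1 that fell (log2 fold change -0.41, edgeR adjusted p = 0.00449). The count was 4 adjusted over the list alone and 7 with the block. Those 7 included Nfkb1, Rela, Nfkbia and Tnfaip3 as well as Relb and Nfkb2. The list's camera adjusted p was 0.0635, or 0.0121 with the block and 0.208 with the block and an estimated correlation. Of 11 lymphoid stroma genes, Tnfsf13b, which encodes the B cell factor BAFF, rose (0.53), Enpp2 fell (-0.41), and the list did not pass (camera adjusted p = 0.211). With adjustment over the list alone the counts were 4 and 1, and with the block 3 and 2.

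None of the signalling and matrix lists passed camera in the main test without the block, and their called members are given by list. Some members are shared with the fibroblast lists and are counted again here. Wnt4, Frzb, Bmp4, Foxf2 and Cxcl14 are in the subepithelial list, Dkk3, Grem1, Rspo3 and C3 in the crypt-base list, and Fn1 and Dcn in the adventitial list. Of 11 retinoic acid genes 2 rose and 3 fell (3 and 3 adjusted over the list alone). Aldh1a3, which makes retinoic acid, rose (0.72), as did Rdh10 (0.72), while Rarg fell (-0.49). Of 16 Wnt genes 3 rose and 2 fell (3 and 7 adjusted over the list alone, 3 and 5 with the block), with Frzb higher (0.54) and Dkk2 lower (-0.70). Of 17 BMP genes 2 rose, Bmp4 (0.40) and Twsg1 (0.30), and 4 fell (2 and 4 adjusted over the list alone, 4 and 5 with the block). Of 11 Hedgehog genes Foxf2 rose (0.45) and the co-receptors Cdon (-1.63) and Boc (-0.37) fell (4 and 3 adjusted over the list alone, 4 and 4 with the block). Hpgd, a prostaglandin-degrading enzyme, was the 1 of 15 prostaglandin genes that fell (-0.56), with 2 rising and 1 falling adjusted over the list alone and 5 and 2 with the block. Notch1 was the 1 of 13 Notch genes that fell (-0.34), with 1 and 2 adjusted over the list alone and 1 and 3 with the block.

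Of 20 interstitial matrix genes 3 rose and 3 fell (6 and 7 adjusted over the list alone, 7 and 8 with the block), Tnc rising (0.50) and Postn (-0.86) and Lum (-0.43) falling. Of 16 basement membrane genes Nid2 (0.60) and Lamb1 (0.28) rose and Col4a4 fell (-1.05), with 3 and 3 adjusted over the list alone and 5 and 5 with the block. Of 22 chemokines and cytokines 2 rose and 2 fell (5 and 4 adjusted over the list alone, 7 and 6 with the block). Cxcl16 rose (0.54), and the neutrophil chemokines Cxcl1 (-0.52) and Cxcl2 (-1.25) fell. Of 11 complement genes 3 fell, C3 (-0.49) and C7 (-0.44) among them, also 3 adjusted over the list alone, and that list's camera adjusted p was 0.140, or 0.0314 with the block and 0.580 with the block and an estimated correlation. Of 12 mural genes Cspg4 rose (0.66) and Mcam (-1.89) and Steap4 (-0.60) fell (2 and 3 adjusted over the list alone, and the same counts with the block). By edgeR 0 of 21 interferon-stimulated and 0 of 16 proliferation genes passed, 0 had an unadjusted p under 0.05 in either list, and DESeq2 and limma-voom called 0. The block called 1 interferon-stimulated gene. H2-D1, one of a family of similar genes, had a log2 fold change of 0.07 and Pcna -0.12.

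RNA of the quality lists also differed. All 9 tested mitochondrially encoded genes fell, the ribosomal RNAs mt-Rnr2 (-0.56) and mt-Rnr1 (-0.55) being the most abundant. The mitochondrial share of counts was 4.57% ± 0.321 in YFP+ and 6.45% ± 0.907 in YFP- (SD, n = 4 each). Most of that share was not protein-coding. Mitochondrial protein-coding genes held 0.33% to 0.40% of counts per library in YFP+ and 0.44% to 0.56% in YFP-. Nuclear copies of mitochondrial sequence leave these counts uncertain. The list's camera adjusted p was 0.0684 with an estimated correlation and 0.169 with the block as well. Of 19 early-response genes, 7 fell (11 adjusted over the list alone, 15 with the block), among them Egr1 (-0.36) and Fos (-0.42), with a camera adjusted p of 0.0451 with an estimated correlation and 0.256 with the block as well. Markers of other cells were mixed. Gja1, which is also expressed outside the interstitial cells of Cajal, rose (0.67), and Etv1 had 0.31 (edgeR adjusted p = 0.219, or 0.0276 with the block). Tek fell (-0.77), and Plvap had -0.62 (edgeR adjusted p = 0.120, or 0.0314 with the block). Of 6 genes of interstitial cells of Cajal 1 rose and 1 fell (2 and 1 adjusted over the list alone and with the block). Of 13 endothelial genes 1 fell (1 adjusted over the list alone, 3 with the block), and of 13 haematopoietic genes 1 fell (1 adjusted over the list alone, 2 with the block). The haematopoietic list and that of interstitial cells of Cajal share Kit. Among genes of at least 1 CPM both had the same lowest log2 fold change, -1.82, so the fall in each may be 1 gene counted in both. The blood cell genes Igha (-0.26) and Jchain (-0.18) did not pass, nor did the neuronal Nos1 (edgeR adjusted p = 0.998) and Ret (edgeR adjusted p = 0.640). Igha stood at 125 ± 95.3 CPM in YFP+ and 151 ± 76.4 CPM in YFP- (SD, n = 4 each), so blood cell RNA was present in both fractions. Of 6 neuronal genes 1 fell (3 adjusted over the list alone, 2 with the block), and that list's camera adjusted p was 0.0307, or 0.457 with an estimated correlation and 0.104 with the block. Krt19, shared by epithelium and mesothelium, fell (-3.50), and the mesothelial Rspo1 had -0.64 (edgeR adjusted p = 0.153). Of 4 tested mesothelial genes 1 fell (2 adjusted over the list alone), too few for the list test.

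Some calls needed all 8 libraries in the test without the block. Bmp4, Boc, C3, Cspg4, Dkk3, Egr1, Enpp2, Fbln1, Fos, Foxf2, Krt19, Lamb1, Lmod1, Ly6c1, Notch1, Rarg, Steap4, Tek, Twsg1 and mt-Rnr1 each lost its call without at least 1 library, with edgeR adjusted p up to 0.151, that of Fos. Tek lost it without YFP+ replicate 3, and Lmod1 and C3 without YFP+ replicate 3 or YFP- replicate 4. Libraries were not removed in turn with the block. Over all 8 libraries, 0 of the 63 named genes called without the block lost that call with it.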

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

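All of the tests of explanations in this part, and the split count with an estimated correlation, were chosen or worded after the results were seen.

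Single libraries stood apart from the other 3 of their group in 19 of 208 sets of 4 values, where chance gives about 1 in 20, or 10.4. YFP- replicate 2 was high for Nkain2 (54.1 CPM), L1cam (41.1 CPM), Slc35f1 (85.0 CPM), Kcna2 (59.0 CPM), Nos1 (10.8 CPM) and the subepithelial fibroblast list (mean log2 CPM 6.35), and low for Lamb1 (1303 CPM). YFP+ replicate 2 was high for Kcna1 (0.781 CPM), Kcna2 (3.13 CPM) and Cd81 (46.0 CPM), and low for the LTβR and NF-kB list (mean log2 CPM 6.20). YFP- replicate 1 was high for the retinoic acid list (5.93) and low for the mitochondrial list (10.2). YFP- replicate 4 was high for Egr1 (3003 CPM) and for its total (28688906 counts), and low for the smooth muscle list (5.09). The remaining 3 were a high Kcnk3 in YFP- replicate 3 (11.1 CPM), a high Birc3 in YFP+ replicate 1 (243 CPM) and a low Nid2 in YFP+ replicate 4 (105.5 CPM).

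Glial genes were lower in YFP+. More of every other cell type that the CD45 and CD31 gates keep in the YFP- libraries would lower their markers in YFP+. How far each falls depends on its level in the remaining cells, so unequal falls do not exclude this. The glial genes of at least 1 CPM ran from -6.39 to -1.94 on the log2 scale and mural genes from -1.89 to 0.79. Smooth muscle genes ran from 0.15 to 1.04, opposite to what more smooth muscle in YFP- would give by itself. The glial median differed from that of 48 genes of the 6 kept lists by -3.68 (two-sided permutation p = 1e-05, or 5e-05 after correction for the 5 versions of this comparison run). The permutations shuffled genes, which are not independent (estimated correlation 0.29 in the glial list), so their p-values do not decide the question. More glia, epithelium, neurons, interstitial cells of Cajal and mesothelium together stays open, because against the 20 genes of those 4 other lists the difference was -1.33 (permutation p = 0.0431, corrected 0.216), and the epithelial median was -2.95 over 14 genes against -3.56 for glia. The other versions gave -2.84 with mural but not smooth muscle genes (corrected permutation p = 0.004). The corrected permutation p was 5e-05 both with the endothelial and haematopoietic genes, whose cells the gates are meant to remove (-2.95), and without epithelium, neurons and mesothelium, left out with their medians in view (-3.26). YFP- replicate 2 alone does not account for the pattern, since without it the glial median was -3.34. That the YFP gate leaves out enteric glia is a hypothesis consistent with 9 of 11 glial genes having a YFP+ mean under 0.25 of the YFP- mean, which restates the pattern more than it tests it and leaves the epithelial genes unaccounted for.

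Mitochondrially encoded and early-response RNA was lower in YFP+. Handling of the cells before lysis cannot be told apart from the gate, because any difference in it between the fractions would follow the groups. The early-response median was -0.40. A difference between the cells themselves stays open and untested.

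More genes were lower than higher in YFP+. A scaling error shifts all genes alike, and the tables argue against it as the whole cause, since 132 genes were lower and 0 higher at least 4-fold, and after a common shift of 0.10 on the log2 scale that balanced all calls (394 higher, 384 lower), 195 genes were still lower and 24 higher at least 2-fold (at least 83.8% lower with any library left out and its own shift). For changes under 2-fold normalization cannot be told apart from other explanations, because the 2 other scalings, under which at least 68.5% of those calls were lower, moved the median of all genes by at most 0.0053 and so did not test it. RNA of enteric glia in the YFP- libraries may add to the genes lower at least 2-fold. Of the 217 such genes outside the glial list, 69.1% were raised further in YFP- replicate 2, where the glial score was highest. Among genes past no threshold the share was 49.1% (Fisher's exact p = 4.04e-09, across genes, which are not independent). The glial list itself was raised there in 63.6% of its 11 genes, so the share does not single out a glial source. For genes lower by less than 2-fold the share was 51.9% and their source cannot be told apart. The test rests on that 1 library. Its mean log2 CPM was also the highest of YFP- for neurons (1.51), interstitial cells of Cajal (2.91) and mesothelium (1.30), sources that stay open too. It was also the highest for mural cells (4.70) and smooth muscle (5.69). Median log2 fold changes of the mural and smooth muscle genes of at least 1 CPM were 0.09 and 0.48. Over all tested mural genes the mean was -0.10, and that list did not pass (camera adjusted p = 0.861). For endothelium (0.83) and haematopoietic cells (1.49) YFP- replicate 2 was the lowest of YFP-, and for epithelium it lay below the highest (1.71 against 1.95).

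Of the 35 splits of the 8 libraries into groups of 4, 1, the real one, gave 697 calls, and the highest other gave 14. For changes of at least 2-fold 1 split reached 240, and the highest other gave 7. That excludes chance only if libraries can be exchanged across pairs. The replicate numbers pair the samples, and the 8 splits that part all 4 pairs are too few for a share under 0.05. Among them the highest other gave 1 call and 1 change of at least 2-fold, and with the block 0 calls against the real 1880. The 27 other splits keep at least 1 pair together. Chance cannot be excluded for the 9 lists past camera at the preset correlation, which 6 of 35 splits reached, the real one included, the highest other giving 15, and which 3 of the 8 reached. With an estimated correlation 1 of the 35, the real one, reached 4 lists, and the others gave 0.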

How the results depend on the processing

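No direction of the 697 called genes or of a list past the threshold turned over under any alternative that gave it a value. Ltbr stayed past no threshold under all of them, its log2 fold change running from 0.03 to 0.17 with a library left out. With the replicate block 597 genes were higher and 1283 lower. Among named genes the block added Etv1 and Plvap and changed no other call. Among lists at the preset correlation it added the LTβR list and the complement list, ended the call of the neuron list and changed no other. Without a filter 309 were higher, 934 lower and 385 changed at least 2-fold. DESeq2 gave 279, 830 and 392. DESeq2 with the block, added after seeing the data, gave 518, 1236 and 442, the counts in the authors' deposited table being 518 and 1236. With both libraries numbered 2 left out, also added, 141 were higher and 452 lower, and 12 named genes (edgeR adjusted p up to 0.224) and the neuron list lost their call while the LTβR and complement lists gained one. With the block too the counts were 500 and 1050. Of the 73 named genes besides Ltbr, 71 then stayed as in the main test and 2 gained a call. Among lists 2 gained a call and 1 lost it. Under limma-voom 3 named genes and the neuron list lost their call and the LTβR list gained one. The cause of these shifts was not tested. Leaving out 1 library gave 88 to 156 higher, 339 to 521 lower, 185 to 267 changed at least 2-fold and 9 to 11 lists. Lists past the threshold fell from 9 to 4 with an estimated correlation. With the block and an estimated correlation only the glial list passed (camera adjusted p = 0.0298). The crypt-base fibroblast, epithelial and early-response lists then lost their call (camera adjusted p = 0.336, 0.169 and 0.256). Of the 73 named genes besides Ltbr, 21 lost their call in at least 1 of the runs without a library and without the block, Lamb1 in all 8. Genes under a few CPM, most of the epithelial list among them, may be limited by depth, which was not tested.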

Other observations

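Both lists in this part were written after the calls were seen, so their p-values are not independent evidence. Of 20 tested imprinted genes, 5 fell in YFP+ and none rose, with 9 falling under the replicate block. The 5 were Mest (log2 fold change -1.05), Peg10 (-0.65), Plagl1 (-0.64), Airn (-0.40) and the long noncoding RNA Meg3 (-0.31). Their median log2 fold change was -0.29 (camera p = 0.0128 with an estimated correlation, 0.0499 with the block as well). Of 29 tested genes inducible by NF-kB, 7 fell and none rose. Nfkbiz (-0.67), Tnfaip6 (-0.60) and Rel (-0.49) were among them, as were Birc3, Cxcl1 and Cxcl2, already counted in the fixed lists. Relb, Nfkb1, Il6 and Icam1, among other members, are in the fixed lists too, so this list in part repeats them. With the block 20 of the 29 genes fell and 2 rose. Their median was -0.31 (camera p = 0.0313 with an estimated correlation, 0.0712 with the block as well). Members of the quality lists fell too. The early-response list, which shares Ier3 with them, had a median of -0.40 with all 19 members negative and 7 fallen, or 15 with the block (camera adjusted p = 0.0451 with an estimated correlation, 0.256 with the block as well), and all 9 tested mitochondrially encoded genes fell (median -0.59, camera adjusted p = 0.0684 with an estimated correlation, 0.169 with the block as well).

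Gm11084, a predicted gene singled out after its values were seen, had 362 CPM in YFP- replicate 4 and between 0.544 and 3.41 CPM in the other libraries. Its log2 fold change of -5.66 did not pass (edgeR adjusted p = 0.361).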
